A study of Pomacea canaliculata with 34 samples.

How the data were processed

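RNA was measured in whole embryos and hatchlings of the apple snail Pomacea canaliculata, a freshwater gastropod with camera-type eyes. Per the labels' protocols, embryos were taken out of their eggs, RNA was extracted with Trizol and polyadenylated RNA was selected for sequencing. The 34 libraries cover 10 points of development, with 3 libraries at each of Stage 2 to Stage 7 and 4 libraries at each of Stage 8, Stage 9, Stage 10 and the hatchling. Stage and replicate number were taken from the sample titles. The labels do not say whether libraries of one stage came from separate clutches or from 1 pool of embryos, so p-values measure only the spread between these libraries, which may be technical.

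The authors deposited 1 table of whole-number read counts per gene and library, with no normalization. STAR is named in the submitters' processing notes. Its version, the counting settings, the genome build, the annotation, strandedness and the treatment of reads that map to several places are not given in the sources used here. Genes that share reads with a near-identical copy or overlap another gene are therefore uncertain, and they cannot be told from the rest without sequence.

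The table lists 21131 genes by NCBI LOC identifier. All 21131 matched a gene symbol of the reference table of assembly ASM307304v1 of this species, and all were protein coding there. None of the 13 mitochondrial protein-coding genes of that table is among them. The symbols equal the identifiers, and neither the counts nor the reference table pairs an identifier with a product name, so 0 genes could be given a function. The 28 lists of genes that had been fixed by product name before the data were examined (eye transcription factors, phototransduction, crystallins, nervous system, muscle, cilia, shell, cell cycle, signalling pathways and others) could not be applied, and no gene list was tested. Because the build behind the counts is not named, the reference table was used only for gene symbols and for the order of genes, and no coordinates are given.

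Total reads in genes ran from 13392123 to 95942469 per library. No 2 libraries were identical. Over the 42 pairs of libraries of one stage, the chi-square statistic per gene (genes with 20 or more reads in the pair) ran from 10.0 to 188, where sampling noise alone gives about unity, so no library was counted as a copy of another.

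The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were kept with filterByExpr (minimum count 10, by stage), which left 17441 genes and removed 3690, of which 334 had 0 reads in every library. Libraries were scaled by TMM, and 1 coefficient per stage was fitted to all 34 libraries, which leaves 24 residual degrees of freedom. The hatchling was compared with Stage 2, each stage with the one before it, and all stages in 1 F-test. P-values were adjusted by the Benjamini-Hochberg method over genes within each comparison, and an adjusted p under 0.05 is a call. The standard error of a log2 fold change was obtained from the fold change and the F statistic. Levels are CPM values on TMM-scaled library totals, given as mean ± SD over the libraries of a stage.

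Genes were named by a rule fixed before the data were examined. With no product names, it allowed at most 2 identifiers up and 2 down per comparison. These were the called genes of the largest log2 fold change with 10 CPM or more in the higher stage, at least 10 reads over the libraries of the lower stage, and no overlap in CPM between the libraries of the compared stages. The genes of highest level at a stage and the genes with an extreme at an inner stage were added after the data were examined. A gene has such an extreme if its estimated level was at least 2-fold higher (or lower) at one of Stage 3 to Stage 10 than at both Stage 2 and the hatchling. The p-values used were those for any difference. The larger p of the 2 comparisons was kept, the smallest over the 8 inner stages was multiplied by 8, and the result was adjusted over genes. The counts of genes that only rose, only fell or did both over the steps were also chosen after the data were examined.

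Genes detected per library were counted after each library was thinned at random to 13392123 reads, the lowest total, and the groups were compared with a two-sided exact permutation test (SciPy 1.17.1). Thinning serves this comparison because late stages were sequenced more deeply. The position of a library between its neighbouring stages is its projection on the line from the mean log2 CPM of the stage before to that of the stage after. Similarity of libraries was measured by Spearman correlation of log2(CPM + 1) over the 17441 tested genes, which are not independent replicates.

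The tests were tried on simulated data drawn from the genes' real means, spreads and library totals, with 65 to 67 genes changed by each of 3 fold sizes at Stage 6 and as many others in the hatchling, among 17196 genes. For Stage 6 against Stage 5, edgeR recovered 51.5%, 68.7% and 83.1% of the genes changed 1.5-fold, 2-fold and 4-fold, and 6.29% of its 143 calls were false. For the hatchling against Stage 2 the shares were 58.5%, 74.2% and 84.8%, with 4.03% false. All 41 genes with a 4-fold change at Stage 6 and 10 CPM or more were recovered in the step test, which is 100%, and 95.1% of them as inner-stage extremes. Of the 9 such genes below 1 CPM, 22.2% were recovered in the step test and 0% as inner-stage extremes, too few genes for a firm share. With DESeq2 the false shares were 16.4% for Stage 6 against Stage 5 and 9.64% for the hatchling against Stage 2. For the test over all stages the DESeq2 share was 30.8%. In the simulation all other genes kept 1 mean over all stages, and as many genes rose as fell. Most real genes varied over the stages, so these shares need not hold for the real data. Scaling was not tried on data in which most genes change.

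Replicates carry like numbers in every stage, but the labels do not say that a number marks a shared clutch, batch or day. The median log2 fold change of all genes between the hatchling and Stage 2 was 0.565 with TMM, 0.64 with RLE and 1.01 with library totals. For Stage 3 against Stage 2 it was 0.0211, 0 and 0.118, for Stage 5 against Stage 4 it was 0, 0 and 0.117, and for Stage 8 against Stage 7 it was 0.0347, 0.138 and 0.0849. Changes are given relative to the TMM scale. The alternatives fixed before the data were examined were RLE size factors, library totals without scaling, no low-count filter, a stricter filter (1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom (limma 3.58.1), a replicate block, a fit of only the compared stages, a 2-fold minimum change and leaving out each library. Thinning, other detection limits and other limits for switched-on genes were added later.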

Results

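The series follows gene expression through the embryonic development of Pomacea canaliculata, an apple snail introduced in the series title as a system for the regeneration of camera-type eyes. Polyadenylated RNA of whole embryos was sequenced at Stage 2 to Stage 10 and in hatchlings. Each of Stage 2 to Stage 7 had 3 libraries, and Stage 8, Stage 9, Stage 10 and the hatchling had 4 each. Total reads in genes ran from 16608796 to 23030901 per library at Stage 2 to Stage 7, from 13392123 to 51823625 at Stage 8, from 17466424 to 41110722 at Stage 9, from 27995708 to 88674538 at Stage 10 and from 31025373 to 95942469 in the hatchling. The comparisons the design implies are the hatchling against the first stage sampled and each stage against the one before it. Genes carry only LOC identifiers here, with no product names, so levels and changes are described without functions.

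Libraries ordered by stage, apart from those of Stage 9 and Stage 10. The first principal component of log2 CPM held 73.0% of the variance and the second 10.5%, and the stages lay along a single arc from Stage 2 to the hatchling. On the first component the libraries of Stage 9 (143.9 to 152.3) and Stage 10 (143.3 to 158.2) overlapped. For 32 of the 34 libraries the closest other library was one of the same stage. The exceptions were replicates 2 and 3 of Stage 5, which were closest to Stage 6 libraries. Spearman correlations within a stage ran from 0.976 in the hatchling to 0.993 at Stage 6. The median correlation between neighbouring stages was highest from Stage 5 to Stage 6, at 0.989, and lowest from Stage 10 to the hatchling, at 0.954. Between Stage 2 and the hatchling it was 0.667.

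**Figure D1:**
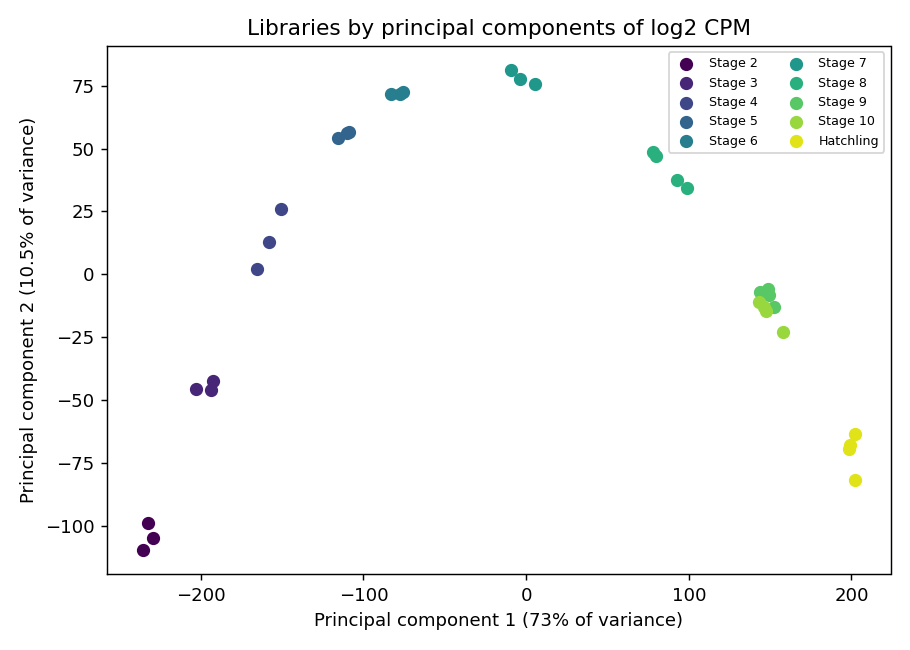
Principal components 1 and 2 of log2 CPM over 17441 genes, 1 point per library, coloured by stage. The 34 libraries follow an arc from Stage 2 to the hatchling, along which Stage 9 and Stage 10 overlap.

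The number of genes in use was compared at equal depth. With every library thinned to 13392123 reads, 11820 ± 61.2 genes (SD, n = 3) had 10 reads or more at Stage 2. The count was 13317 ± 64.6 (n = 3) at Stage 5, 15067 ± 152 (n = 4) at Stage 8 and 16149 ± 57.3 (n = 4) in the hatchling. The hatchling exceeded Stage 2 by 4329 genes, and every hatchling library was above every Stage 2 library. The exact permutation test, with a two-sided p of 2 times the smaller one-sided p, gave p = 0.0571. This is the smallest that this form of the test allows for 3 against 4 libraries, so it could not pass 0.05. The 10 most abundant genes of a library took 6.53% ± 0.178 of its reads at Stage 2 (n = 3), 4.79% ± 0.115 at Stage 6 (n = 3) and 6.81% ± 1.5 in the hatchling (n = 4). Between Stage 2 and the hatchling the same form of the exact permutation test gave p = 0.857 (two-sided) for this share. It could not pass 0.05 for any difference.

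**Figure D2:**
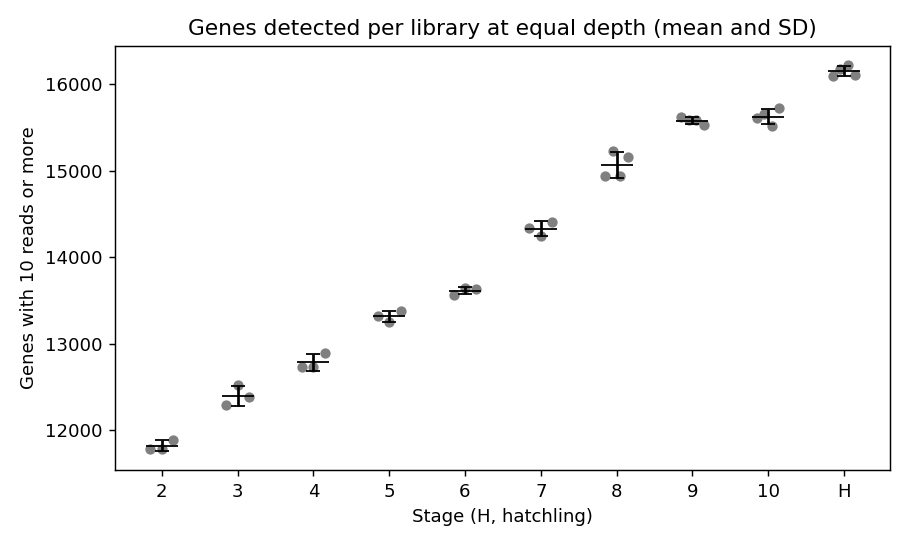
Genes with 10 reads or more per library (y axis, which does not start at 0) after thinning to equal depth, by stage (x axis), with 1 point per library and the mean and SD. The stage means run from 11820 at Stage 2 to 16149 in the hatchling.

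The genes of highest level changed over the series. LOC112562047 had the highest mean from Stage 2, at 16220 ± 227 CPM (n = 3), to Stage 6, at 7817 ± 204 CPM (n = 3). At Stage 7 it stood at 6556 ± 258 CPM, LOC112575079 at 6343 ± 302 CPM and LOC112561353 at 6245 ± 767 CPM (n = 3 each), which differ by less than the spread between libraries. LOC112562047 stood at 4390 ± 190 CPM in the hatchling (n = 4). LOC112574335 was second at Stage 2 with 11630 ± 775 CPM (n = 3) and stood at 2590 ± 138 CPM in the hatchling (n = 4). LOC112561353 led Stage 8 with 16410 ± 1130 CPM (n = 4), against 1.65 ± 0.158 CPM at Stage 2 (n = 3). At Stage 9 LOC112575079 stood at 12390 ± 1850 CPM and LOC112561353 at 11370 ± 2910 CPM, at Stage 10 LOC112560121 at 9791 ± 1830 CPM and LOC112575079 at 8648 ± 983 CPM, and in the hatchling LOC112575079 at 9890 ± 3770 CPM and LOC112560121 at 9420 ± 4270 CPM (n = 4 each). At each of these stages the genes of the pair differed by less than the spread between libraries.

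Nearly all tested genes varied over development. The F-test over all stages (edgeR quasi-likelihood, Benjamini-Hochberg adjustment) called 16632 of 17441 genes, or 95.4%. Of these, 5174 genes (31.1%) had their highest stage mean in the hatchling and 3749 (22.5%) at Stage 2. Stage 3 held the highest mean of 1538 genes (9.25%) and Stage 9 that of 1494 (8.98%), while Stage 5 held it for 381 (2.29%). These are rankings of means, with no test between stages.

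The hatchling was compared with Stage 2 to span the whole series. Of 17441 genes, 15031 differed (86.2%), with 9065 higher and 5966 lower in the hatchling, and 7444 rose and 3641 fell by 2-fold or more. LOC112556452 rose from 0.357 ± 0.0780 CPM at Stage 2 (n = 3) to 4211 ± 1150 CPM (n = 4), a log2 fold change of 13.50 (SE 0.448, edgeR adjusted p = 3.24e-21). LOC112564430 rose from 0.600 ± 0.162 to 3688 ± 1210 CPM (log2 fold change 12.56, SE 0.369, edgeR adjusted p = 2.27e-22). LOC112556192 was at 365 ± 82.3 CPM at Stage 2 and at 0.0382 ± 0.0422 CPM in the hatchling (log2 fold change -12.59, SE 0.359, edgeR adjusted p = 1.24e-22). LOC112556072 was at 227 ± 57.0 CPM at Stage 2 and at 0.148 ± 0.0868 CPM in the hatchling (log2 fold change -10.56, SE 0.385, edgeR adjusted p = 2.73e-20). The lower levels of these 4 genes rest on 12 to 31 reads over all libraries of the stage, and 10 of the 12 hatchling reads of LOC112556192 were in replicate 1, without which its log2 fold change was -14. The share of calls that were higher in the hatchling was 60.3% with TMM scaling, 62.0% with RLE and 70.1% with library totals, because the median log2 fold change of all genes was 0.57, 0.64 and 1.01 under these scalings.

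Some genes were read at one end of the series only. In 295 genes no read was found among the 55988658 reads of the Stage 2 libraries, which allows up to 3 reads in that total, while every hatchling library had 10 CPM or more. The count was 615 where up to 3 reads over the Stage 2 libraries were allowed, a limit chosen after seeing the data. No gene met the converse rule, with 0 reads among the 198257416 reads of the hatchling and 10 CPM or more in every Stage 2 library. The hatchling libraries together were deeper than those of Stage 2, so a rarely read transcript was more likely to be found in them. Of the 295 genes, 91 first reached a mean of 10 CPM in the hatchling, 86 at Stage 9, 58 at Stage 8 and 36 at Stage 7.

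The 9 steps between neighbouring stages differed in the number of genes called. Stage 8 against Stage 7 gave the most, 8043 genes, followed by Stage 3 against Stage 2 with 6797, the hatchling against Stage 10 with 6309 and Stage 7 against Stage 6 with 5307. Stage 5 against Stage 4 gave 3958, Stage 9 against Stage 8 gave 3942 and Stage 4 against Stage 3 gave 3733. Stage 10 against Stage 9 gave 898 and Stage 6 against Stage 5 gave 596. With limma-voom the hatchling against Stage 10 gave the most, with 8586 against 7566 for Stage 8 against Stage 7. With a test against a 2-fold minimum the order turned at both ends. Stage 3 against Stage 2 then gave the most, with 1082 against 809 for Stage 8 against Stage 7, and Stage 10 against Stage 9 the fewest, with 14 against 18 for Stage 6 against Stage 5. Counts of calls at steps with 3 and with 4 libraries per stage rest on different numbers of libraries. The change from 3 to 4 libraries, with a wider range of totals, falls at the step from Stage 7 to Stage 8. A difference in preparation or sequencing at that step, if there was one, cannot be told from stage.

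**Figure D3:**
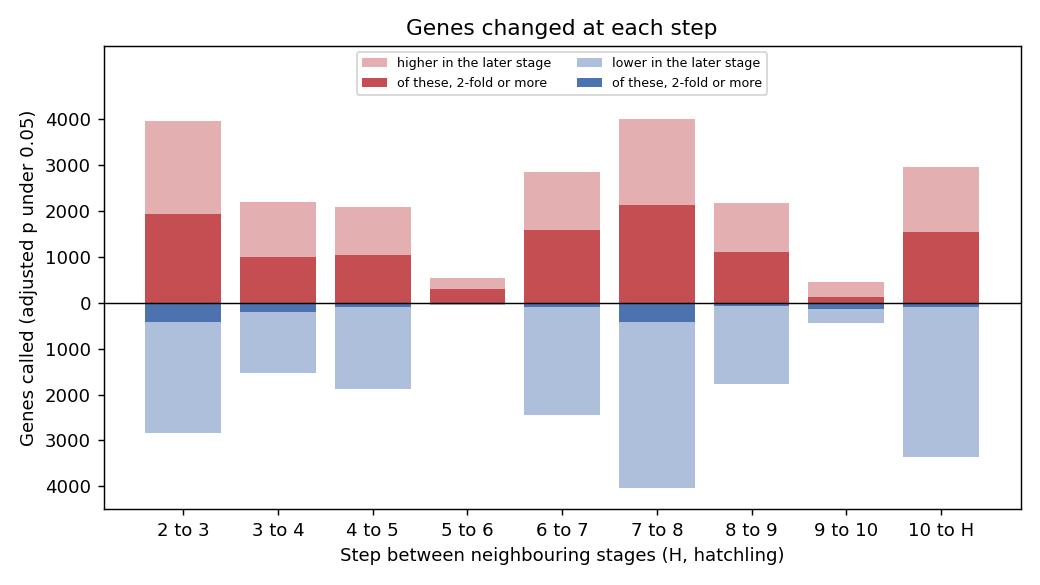
Genes called at each step (adjusted p under 0.05), with those higher in the later stage above 0 and those lower below 0. The darker part of each bar changed by 2-fold or more. The step from Stage 7 to Stage 8 has 8043 calls and that from Stage 5 to Stage 6 has 596.

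From Stage 2 to Stage 3, 3960 genes rose and 2837 fell, of which 1931 and 429 changed by 2-fold or more. LOC112573645 rose from 4.98 ± 2.25 to 3339 ± 533 CPM (n = 3 each, log2 fold change 9.38, SE 0.406, edgeR adjusted p = 4.95e-16), and LOC112571323 rose from 0.229 ± 0.144 to 130.5 ± 49.8 CPM. LOC112553858 fell from 569 ± 156 to 40.4 ± 12.3 CPM (log2 fold change -3.82, SE 0.288, edgeR adjusted p = 2.53e-11), and LOC112567077 fell from 27.6 ± 11.8 to 2.07 ± 0.283 CPM. With TMM 58.3% of the calls rose, with library totals 71.1%, with RLE 49.3% and with DESeq2 49.1%, so the last 2 turned the excess of rises into one of falls. From Stage 3 to Stage 4, 2198 genes rose and 1535 fell. LOC112561402 rose from 0.249 ± 0.154 to 109 ± 40.5 CPM and LOC112565028 from 0.780 ± 0.241 to 282 ± 148 CPM. The log2 fold change of LOC112561402 was 8.73 with all libraries and 9.32 without replicate 2 of Stage 3. LOC112553858 fell again, from 40.4 ± 12.3 to 3.95 ± 1.65 CPM, and LOC112554455 fell from 10.1 ± 2.60 to 1.002 ± 0.711 CPM. Rises made up 58.9% of the calls, and 75.6% with library totals. In the fit of these 2 stages alone the count of calls was 1626.

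From Stage 4 to Stage 5, 2089 genes rose and 1869 fell, with 1036 and 98 changed by 2-fold or more. LOC112560630 rose from 1.56 ± 1.95 to 104 ± 34.6 CPM (n = 3 each, log2 fold change 6.13, SE 0.592, edgeR adjusted p = 1.46e-08), and LOC112560562 rose from 3.55 ± 4.14 to 206 ± 126 CPM (log2 fold change 5.91). Their Stage 4 libraries stood at 0.655, 0.213 and 3.80 CPM and at 1.86, 0.534 and 8.27 CPM, and without replicate 3 of Stage 4 the log2 fold changes were 7.91 and 7.45. Without replicate 1 of Stage 5 that of LOC112560562 was 5.29. LOC112561451 was at 960 ± 822 CPM at Stage 4 and at 28.3 ± 3.03 CPM at Stage 5 (log2 fold change -5.09, SE 1.14, edgeR adjusted p = 0.00153), and its Stage 4 libraries stood at 271, 1870 and 739.5 CPM. Without the second of these its log2 fold change was -4.15. Libraries of this gene also differed widely within other stages. They stood at 22.87, 565.2 and 623 CPM at Stage 3 and at 328, 35.93 and 33.39 CPM at Stage 6. At Stage 7 they stood at 30.03, 206.1 and 26.25 CPM. From Stage 8 to the hatchling they lay between 21.6 and 57.97 CPM. A change between Stage 4 and Stage 5 cannot be told from such differences between libraries, so none is read from this call. LOC112576570 fell from 13.1 ± 3.06 to 1.82 ± 0.899 CPM. Of the calls 52.8% rose, and 78.7% with library totals. With limma-voom 44.4% rose, which turned the excess of rises into one of falls. The count of calls was 3958 with all libraries, 2546 without replicate 1 of Stage 4 and 1817 in the fit of these 2 stages alone.

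From Stage 5 to Stage 6, 540 genes rose and 56 fell, of which 305 and 5 changed by 2-fold or more. Rises thus made up 90.6% of the calls. The number of falls moved with the setting, with 150 in DESeq2 (82.9% of the calls rose) and 7 without replicate 3 of Stage 6. In the fit of these 2 stages alone the count of calls was 381, with 290 genes higher and 91 lower. With limma-voom the count of calls was 223. LOC112564630 rose from 2.26 ± 0.989 to 21.5 ± 8.58 CPM (n = 3 each, log2 fold change 3.25, SE 0.3, edgeR adjusted p = 3.3e-08), and LOC112564731 rose from 1.93 ± 0.801 to 16.6 ± 7.28 CPM. LOC112567041 fell from 35.8 ± 7.78 to 16.9 ± 2.19 CPM (log2 fold change -1.08, SE 0.187, edgeR adjusted p = 0.000558). LOC112567977 fell from 18.02 ± 3.98 to 8.61 ± 2.97 CPM (edgeR adjusted p = 0.0227). The call of LOC112567041 was lost only in the test against a 2-fold minimum (edgeR adjusted p = 1). The call of LOC112567977 was lost in that test too, without replicate 2 or 3 of Stage 5 (edgeR adjusted p = 0.0601 and 0.132), without replicate 2 or 3 of Stage 6 (0.0694 and 0.183) in the fit of these 2 stages alone (0.0814) and with limma-voom (adjusted p = 0.226), and the adjusted p over all alternatives ran from 0.00381 to 1. The count of calls fell to 377, 394 and 354 without replicates 1, 2 and 3 of Stage 5, and to 319 and 357 without replicates 2 and 3 of Stage 6.

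From Stage 6 to Stage 7, 2853 genes rose and 2454 fell, of which 1589 and 86 changed by 2-fold or more. LOC112560121, one of the most abundant genes of Stage 10, rose from 5.67 ± 2.59 to 1024 ± 137 CPM (n = 3 each, log2 fold change 7.50, SE 0.466, edgeR adjusted p = 2.06e-12). LOC112559961 rose from 0.234 ± 0.366 to 81.7 ± 12.2 CPM, with 14 of its 15 Stage 6 reads in replicate 3, and its log2 fold change of 8.47 was 7.86 without replicate 1 of Stage 6 and 11.61 without replicate 3, where it rests on 1 read. LOC112570894 fell from 43.4 ± 6.22 to 4.52 ± 1.69 CPM (log2 fold change -3.26, SE 0.234, edgeR adjusted p = 3.53e-11), and LOC112553993 fell from 23.2 ± 2.26 to 6.73 ± 1.25 CPM. Rises made up 53.8% of the calls, and 66.1% with library totals.

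From Stage 7 to Stage 8, 3998 genes rose and 4045 fell, and 2133 and 417 of them changed by 2-fold or more. LOC112572587 rose from 0.209 ± 0.178 (n = 3) to 27.6 ± 13.8 CPM (n = 4), with a log2 fold change of 7.02 (SE 0.499, edgeR adjusted p = 3.65e-11). LOC112571032 rose from 0.207 ± 0.126 to 23.8 ± 8.26 CPM (log2 fold change 6.80). These 2 genes had 12 reads each at Stage 7, and their log2 fold changes were 7.98 without replicate 1 and 7.42 without replicate 3 of that stage. LOC112566597 fell from 13.1 ± 2.79 to 1.13 ± 0.351 CPM (log2 fold change -3.50, SE 0.389, edgeR adjusted p = 3.49e-08), and LOC112573553 fell from 281 ± 41.1 to 36.3 ± 2.73 CPM. With TMM 49.7% of the calls rose, with RLE 62.8%, with DESeq2 63.4% and with library totals 56%, so which direction held more calls depended on the scaling. In the test against a 2-fold minimum 88.3% rose. From Stage 8 to Stage 9, 2169 genes rose and 1773 fell. LOC112565814 rose from 0.516 ± 0.830 to 31.6 ± 13.3 CPM and LOC112565813 from 0.339 ± 0.147 to 25.9 ± 4.71 CPM (n = 4 each). The log2 fold change of LOC112565814 was 6.48 with all libraries and 7.93 without replicate 2 of Stage 8. LOC112555657 fell from 40.4 ± 26.6 to 9.86 ± 3.28 CPM (edgeR adjusted p = 0.0036), a call lost with limma-voom (adjusted p = 0.0791) and against a 2-fold minimum (0.158), with adjusted p from 0.000522 to 0.158 over all alternatives. LOC112577381 fell from 44.4 ± 22.3 to 11.02 ± 3.64 CPM (edgeR adjusted p = 5.43e-05). Rises made up 55% of the calls, and 45.7% with library totals.

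From Stage 9 to Stage 10, 461 genes rose and 437 fell, with 117 and 125 changed by 2-fold or more. LOC112555712 rose from 12.45 ± 2.76 to 69.3 ± 17.1 CPM (n = 4 each, log2 fold change 2.47, SE 0.411, edgeR adjusted p = 0.00076). LOC112576650 rose from 68.99 ± 74.4 to 304.5 ± 52 CPM (edgeR adjusted p = 0.0188). Libraries of these genes also differed widely within other stages. Those of LOC112555712 stood at 15.27, 54.49 and 25.81 CPM at Stage 6, and those of LOC112576650 at 844.8, 892.4 and 314.7 CPM at Stage 3. Their rises are therefore uncertain. LOC112555741 fell from 21.5 ± 17.4 to 4.71 ± 0.333 CPM (edgeR adjusted p = 0.00385) and LOC112566790 from 20.98 ± 12.1 to 5.19 ± 2.67 CPM (edgeR adjusted p = 0.0157). All 4 calls were lost in the test against a 2-fold minimum, with an edgeR adjusted p of 0.0869 for LOC112555712. Without replicate 3 of Stage 9 the log2 fold change of LOC112576650 was 3.26 in place of 2.14, and without replicate 2 of Stage 9 that of LOC112555741 was -1.54 in place of -2.18. In the fit of these 2 stages alone the last 3 calls were lost, with edgeR adjusted p of 0.0789 for LOC112576650, 0.0509 for LOC112555741 and 0.0553 for LOC112566790, and over all alternatives the highest adjusted p were 0.745, 0.31 and 0.734. The call of LOC112576650 was also lost without replicate 1, 2 or 4 of Stage 9 (edgeR adjusted p = 0.0519, 0.0658 and 0.0666), and that of LOC112566790 without replicate 3 or 4 of Stage 9 or replicate 4 of Stage 10 (0.0632, 0.0553 and 0.0589). With TMM 51.3% of the calls rose, with RLE 38.4%, with DESeq2 38.9% and with library totals 72.8%, so the direction of the excess depended on the scaling. The count of calls was 1740 with DESeq2 and 2399 with limma-voom, 525, 474 and 586 without replicates 2, 3 and 4 of Stage 9, and 494, 561 and 492 without replicates 1, 3 and 4 of Stage 10.

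From Stage 10 to the hatchling, 2950 genes rose and 3359 fell, of which 1550 and 93 changed by 2-fold or more. LOC112570672 rose from 1.65 ± 1.71 to 102 ± 57.3 CPM (n = 4 each, log2 fold change 6.05, SE 0.578, edgeR adjusted p = 9.49e-09). LOC112564945 rose from 0.0860 ± 0.0607 to 13.3 ± 12.1 CPM (log2 fold change 7.28, SE 1.04, edgeR adjusted p = 5.08e-05), with hatchling libraries between 2.15 and 28.7 CPM. Its log2 fold change was 6.58 without replicate 3 of the hatchling, and that of LOC112570672 was 6.82 without replicate 2 of Stage 10. LOC112557629 fell from 181 ± 73.0 to 5.25 ± 3.08 CPM (log2 fold change -5.11, SE 0.423, edgeR adjusted p = 8.93e-10), and LOC112557628 fell from 176 ± 60.6 to 5.42 ± 2.25 CPM. With TMM 46.8% of the calls rose. The excess of falls turned into one of rises with RLE (53.6%), DESeq2 (53.9%), limma-voom (50.1%), the fit of these 2 stages alone (53.5%) and the test against a 2-fold minimum (97.4%, with 687 genes higher and 18 lower).

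Genes were sorted by the direction of their calls over the steps. Of 17441 genes, 6324 (36.3%) rose at 1 or more steps and fell at none, and 4343 (24.9%) fell at 1 or more and rose at none. A further 3905 (22.4%) both rose and fell at different steps, and 2869 (16.4%) were called at no step. The first 2 sets hold 3841 genes called at a single step, which cannot show both directions. Of the 10731 genes called at 2 or more steps, 6826 (63.6%) went 1 way and 3905 (36.4%) both ways. Neighbouring steps share the libraries of a stage, so these calls are not independent of each other.

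Of the 16632 genes called over all stages, 7709 (46.4%) had their highest stage mean at an inner stage, a ranking without a test. A smaller set differed from both ends in the tests, with estimated changes of 2-fold or more. No test against a 2-fold minimum was run for inner stages. Relative to both Stage 2 and the hatchling, 452 genes were at least 2-fold higher at an inner stage, with the smallest p at Stage 7 for 85 of them, at Stage 6 for 81 and at Stage 3 for 77. LOC112557629 reached 995 ± 22.6 CPM at Stage 6 (n = 3), against 13.4 ± 5.75 CPM at Stage 2 (n = 3) and 5.25 ± 3.08 CPM in the hatchling (n = 4, edgeR adjusted p = 4.11e-09). LOC112561435 reached 59.6 ± 11.4 CPM at Stage 5 (n = 3), against 0.396 ± 0.174 and 0.901 ± 0.244 CPM at the ends (edgeR adjusted p = 3.75e-11). The converse held for 252 genes, a count that was 421 with DESeq2 and 153 with limma-voom. LOC112567977 stood at 1.73 ± 0.255 CPM at Stage 7 (n = 3), against 119 ± 34.6 CPM at Stage 2 and 19.1 ± 3.51 CPM in the hatchling (edgeR adjusted p = 1.05e-07). LOC112567192 stood at 1.34 ± 0.562 CPM at Stage 5 against 15.5 ± 16.2 and 18.2 ± 3.08 CPM (edgeR adjusted p = 0.0109). That call rested on replicate 3 of Stage 2, without which the log2 fold change against Stage 2 was -2.28 in place of -3.55 and the edgeR adjusted p was 0.366. With limma-voom the log2 fold change was -2.93 and the adjusted p was 1, and over all alternatives it ran from 2.09e-06 to 1.

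**Figure D4:**
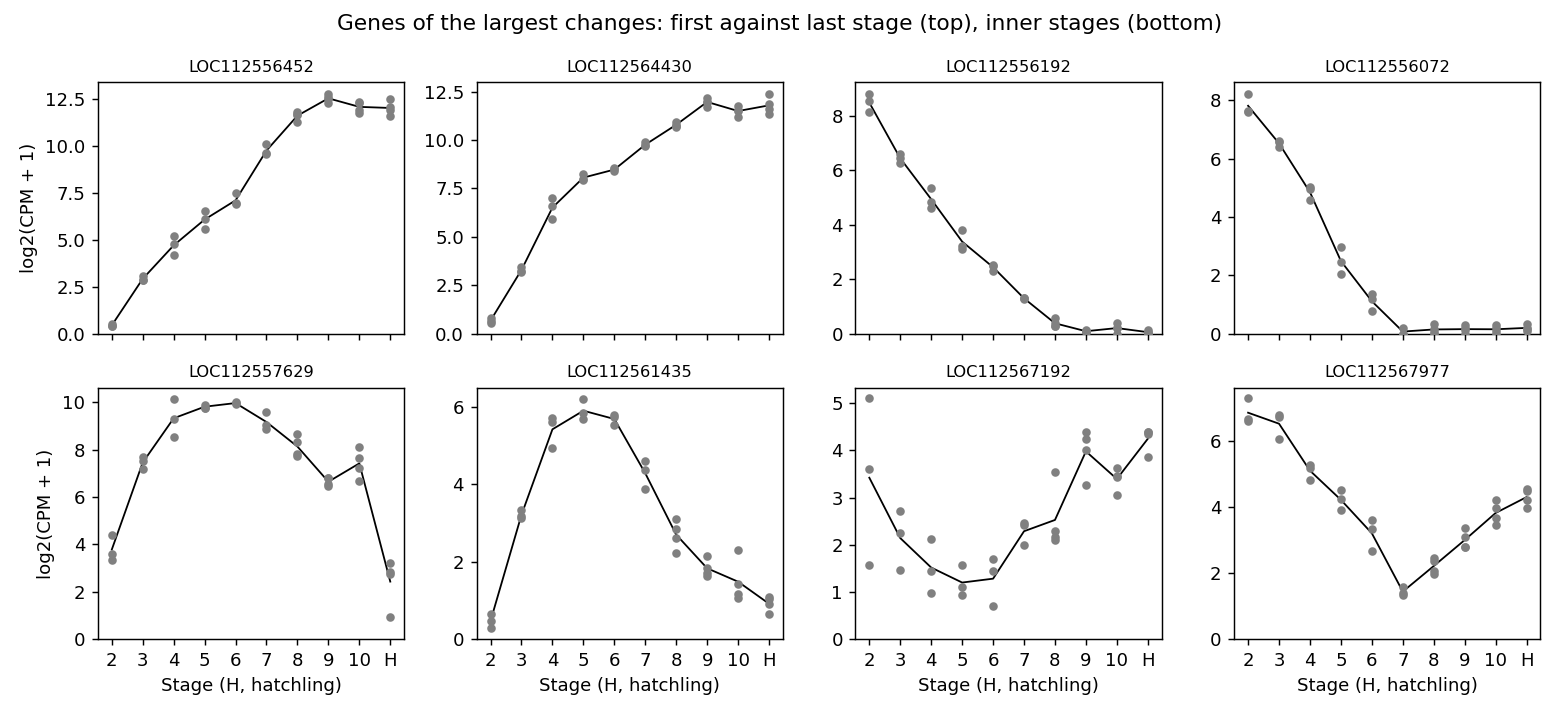
Level of 8 genes as log2(CPM + 1) (y axis) by stage (x axis), with 1 point per library and a line through the stage means. The top row holds the genes of the largest change between Stage 2 and the hatchling, and the bottom row genes with an extreme inside the series, such as LOC112557629, at 995 CPM at Stage 6.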

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

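The splits of the test over all stages and of the hatchling against Stage 10 were first run before their outcome was predicted. In groups of 4 libraries, a library was singled out where its gap to the nearest of the others, divided by the group's range, exceeded Dixon's critical value. Among 58 groups this singled out 5, where chance gives about 2.9, and nothing is read from their number. Genes were checked only at the stages for which they are named. Replicate 1 of the hatchling had 95942469 reads, against 31025373 to 37848728 in the other hatchling libraries. LOC112555712 stood at 43.7 CPM in replicate 2 of Stage 10, against 76.4 to 78.7 CPM in the others. In the hatchling, where it was not checked, replicate 2 stood at 42.71 CPM against 77.03 to 79.68 CPM. LOC112565814 stood at 1.76 CPM in replicate 2 of Stage 8, against 0.0507 to 0.176 CPM in the others. LOC112567192 stood at 13.6 CPM in replicate 2 of the hatchling, against 19.35 to 19.94 CPM in the others. LOC112576650 stood at 180.0 CPM in replicate 3 of Stage 9, against 22.4 to 39.01 CPM in the others. At Stage 8, where it was not checked, replicate 3 stood at 198.3 CPM against 35.83 to 46.41 CPM. Whether such repeats mark an origin shared by replicate number was not tested.

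Other splits of the libraries were counted for the tests over all genes. In 1 of 40 groupings of all libraries drawn, the real one, the test over all stages called as many genes, 16632 against at most 11. For the comparisons of 2 stages the splits were fitted on those stages alone. The real split was the 1 of 35 with as many calls for the hatchling against Stage 2 (14515 against at most 0), Stage 8 against Stage 7 (8109 against 2), Stage 9 against Stage 8 (4375 against 24), Stage 10 against Stage 9 (815 against 8) and the hatchling against Stage 10 (6277 against 4). A share of the splits under 0.05 gave as many calls for these and for the test over all stages. These shares were not adjusted for the number of comparisons. Other splits mix libraries of different stages, which widens the spread within groups, so few calls were likely in them. The splits also cannot separate stage from clutch or pool, so no conclusion on chance is drawn from them. With 3 libraries against 3 there are only 10 splits, too few for such a share. The real values and the highest of the other splits were 5012 and 0 for Stage 3 against Stage 2, 1626 and 2 for Stage 4 against Stage 3, 1817 and 0 for Stage 5 against Stage 4, 381 and 24 for Stage 6 against Stage 5, and 5667 and 1 for Stage 7 against Stage 6.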

How the results depend on the processing

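All counts of calls kept within 1.5 times of the main count with RLE factors, library totals, either low-count filter, the replicate block and thinning to equal depth, while the split between higher and lower calls moved with the scaling. With the replicate block the counts were 14941 for the hatchling against Stage 2, 535 for Stage 6 against Stage 5 and 823 for Stage 10 against Stage 9, and the block changed no call of a named gene. No comparison met the rule for pairing by number: deviations of same-numbered libraries correlated between -0.265 and 0.339 over 33 pairs. In 0 of 10 comparisons did every pair exceed 0.1. Single pairs did, such as replicate 1 of Stage 3 against Stage 2 (0.339) and replicate 2 of Stage 6 against Stage 5 (0.334). Pairing at some steps is therefore not settled. With DESeq2 Stage 10 against Stage 9 gave 1740 calls and 421 genes were lower at an inner stage. With limma-voom these were 2399 and 153, and Stage 6 against Stage 5 gave 223. In fits of only the compared stages, Stage 4 against Stage 3 gave 1626, Stage 5 against Stage 4 gave 1817 and Stage 6 against Stage 5 gave 381. With a 2-fold minimum change, which asks for more by construction, the steps in order from Stage 3 against Stage 2 gave 1082, 452, 296, 18, 534, 809, 473, 14 and 705. Leaving out 1 library gave 319 to 563 calls for Stage 6 against Stage 5 (main 596), 474 to 1016 for Stage 10 against Stage 9 (main 898) and 2546 to 4366 for Stage 5 against Stage 4 (main 3958). The lowest were without replicate 2 of Stage 6, replicate 3 of Stage 9 and replicate 1 of Stage 4. The cause of these moves was not tested. For Stage 4 against Stage 3 the range was 2522 to 4035, and every other count stayed within 1.5 times of its main value. The switched-on genes numbered 615 if up to 3 reads over all Stage 2 libraries were allowed and 441 at 5 CPM, limits chosen, like thinning and those for detection, after seeing the data. The hatchling exceeded Stage 2 by 3422 detected genes at 1 read or more and by 5285 at the deposited depth. Library placement gave 30 to 32 of 34 libraries under 3 alternatives. Named genes kept their direction in all of 431 refits and lost their call in 14, and in 408 refits without 1 library they lost it in 11. Under the stricter filter 1 named gene was not tested. In simulated data 68.8% of 16 genes between 1 and 10 CPM with a 4-fold change were recovered at a step, against 100% of 41 genes at higher levels. Depth and the larger spread of rarely read genes were not told apart. The gene list tests were not run, for lack of product names.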

Other observations

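The patterns below were found in the data and tested on the same data, and the tests of scaling, of equal depth over the steps, of genes near the floor and of shared replicate numbers were chosen after their results had been seen. Among genes that varied over the stages, the stage profiles of directly neighbouring genes had a median correlation of 0.442 over 14430 pairs. The order of genes was that of the reference table. For genes 2, 3, 5, 10, 20 and 50 places apart the medians were 0.253, 0.182, 0.13, 0.0975, 0.0389 and 0.0645, and in 1000 random gene orders the median for direct neighbours lay between 0.0214 and 0.125. Of the 295 genes without a read at Stage 2 and at 10 CPM or more in the hatchling, 75 (25.4%) lay directly beside another of them, against a median of 8 and at most 24 in 1000 random draws. Of the 452 genes higher at an inner stage, 104 (23%) did, against at most 41. For both sets the one-sided permutation p was 0.001, the smallest the draws can give. For the 252 genes lower at an inner stage the number was 16, against at most 20 (one-sided permutation p = 0.016). Of the 3641 genes lower by 2-fold or more in the hatchling than at Stage 2, 1786 (49.1%) lay directly beside another. The random draws gave a median of 1234 and at most 1351 (one-sided permutation p = 0.001). Such grouping was thus not particular to the smaller sets. Among the genes named above, LOC112557629 and LOC112557628 are direct neighbours, as are LOC112565813 and LOC112565814, and LOC112560630 lies between LOC112560121 and LOC112560562.

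Transcription or reads running on from one gene into the next could account for similar profiles of direct neighbours. If limited to direct neighbours, it would leave genes 3 places apart within the range of random orders. Their median of 0.182 lay above the highest of these, 0.114. This argues against running on between direct neighbours only as the whole cause, while part of their value may still come from it. Running on over several genes in a row could give medians that fall with distance, as these did. The comparison with random orders cannot separate that case, which stays open. Reads shared by near-identical copies in tandem, and copies of a gene that are regulated alike, stay open and were not tested, since no sequence was used here.

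Genes that rose by 2-fold or more outnumbered those that fell by as much at 8 of the 9 steps, by 4.5 times at Stage 3 against Stage 2 and by up to 61 times at Stage 6 against Stage 5, where 5 genes fell. At Stage 10 against Stage 9 there were 117 rises and 125 falls, 118 and 143 with RLE, 152 and 118 with library totals and 103 and 94 at equal depth, so the direction at this step depended on the setting. Scaling is one candidate explanation. The smallest shift that would make the counts equal at any of the 8 steps was 0.44 on the log2 scale. The scalings tried differed in their medians by at most 0.118, so the choice among them does not account for the excess. A shift that all of them share was not tested and stays open. The excess remained over 1.5 times at 8 of the 8 steps with all libraries at equal depth, which argues against depth as the cause. Among genes with a mean of 10 CPM or more in the lower of the 2 stages it was over 1.5 times at 8 of the 8 too, with 83 rises and 35 falls at Stage 4 against Stage 3 as the smallest ratio, which argues against genes near the floor as the whole cause. Without this limit that step had 1004 rises and 205 falls. At each of the 8 steps most of the excess in number came from genes under 10 CPM in the lower stage. No biological explanation was tested.

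Stage 8 was singled out from the plot of principal components. Libraries of a stage differed in how far they lay toward the next stage, on a scale with 0 at the mean of the stage before and 1 at the mean of the stage after. The 4 libraries of Stage 8 stood at 0.544, 0.605, 0.522 and 0.655. Their range of 0.133 was 0.123 at equal depth, which argues against depth as the cause, and the deepest and the shallowest library were the 2 farthest along. Same-numbered libraries of Stages 7, 8 and 9 deviated together by a correlation over all tested genes of at most 0.0478, for 7 pairs. This argues against a batch shared by number that moves most genes together. One that shows in few genes stays open. LOC112576650 was highest in replicate 3 at Stage 8 (198.3 CPM against 35.83 to 46.41 CPM) and at Stage 9 (180 CPM against 22.4 to 39.01 CPM). At Stage 7 replicate 3 was its lowest library, at 222.7 CPM. Wider ranges of positions than that of Stage 8 were found at Stage 4 (0.197, with positions 0.437, 0.533 and 0.634) and at Stage 10 (0.158). Differences in age between embryos of one stage may account for such spreads and were not tested, since the labels give no ages.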
